A study of Gallus gallus with 12 samples.

How the data were processed

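Gene expression was measured in the dorsal mesentery, the sheet of tissue that suspends the gut tube from the back wall of the body, in Leghorn chicken embryos at Hamburger-Hamilton stage 21, reached at about day 3.5 of incubation. Each side of the mesentery holds a core of loose mesenchyme covered by a coelomic epithelium, and the labels name 4 compartments: left epithelium, left mesenchyme, right mesenchyme and right epithelium. Per the labels' protocols, frozen blocks were sectioned at 8 µm, the compartments were excised by laser, and the small RNA yields were amplified with the NuGEN WT-Ovation Pico kit and labelled with biotin from 5 ng of total RNA. The series text counts 1939 captured sections in 3 biological experiments, with the material of an experiment pooled for each compartment on an array of its own. There were therefore 12 arrays, with n = 3 biological experiments per compartment and no technical replicates. How many embryos entered an experiment, and how the borders of the compartments were recognised, is not given in the sources used here.

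The authors deposited 1 table of 1-colour Affymetrix intensity values, linear and above 0, made with MAS5 in the GCOS software per the submitters' processing notes, which give no versions. The values showed that the authors had scaled each array to a common level, since the mean of each array after trimming 2% of the values at each end was 500.11 to 500.12, and no quantile normalization had been applied. The array medians ranged from 84.4 to 98.8. The MAS5 detection calls were not used here. As a floor, the 95th percentile of 30 control probe sets without a chicken target was taken on each array. It lay between 20.3 and 34.4 signal units, and 68.2% to 75.2% of the probe sets on an array were above it. The number of arrays limits the precision.

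The table held 38535 probe sets, of which 96 were Affymetrix controls, 746 were named by viral or other accessions and 37693 were chicken probe sets. Names came from the platform annotation of 2016. It gave 1 gene symbol for 27166 chicken probe sets, several for 177 and none for 10350, and the probe sets without exactly 1 symbol were left unnamed. The Entrez identifiers of 26851 probe sets stood in the chicken RefSeq table, through which 0 symbols changed.

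The scaling was kept, 16 was added to each value and log2 was taken, so that the change of a dim gene is understated. Of the 38439 probe sets other than controls, the 23063 whose mean log2 value lay above the 40th percentile, a signal of 47.4, were tested. limma 3.58.1 in R 4.3.3 fitted all 12 arrays in 1 linear model with the compartment and, as a fixed block, the experiment, and moderated the variances with an intensity trend (6 residual and 10.6 prior degrees of freedom). All compartments share this estimate of the spread. The contrasts were left against right within the mesenchyme, left against right within the epithelium, epithelium against mesenchyme over both sides, and the interaction, which is the left-right change in the epithelium minus that in the mesenchyme. Tests were two-sided, with Benjamini-Hochberg adjustment over the 23063 probe sets within a contrast and a threshold of 0.05 on the adjusted p. A plain exact test of 3 arrays against 3 cannot give a p below 0.1.

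The experiment was used as a block because the series text says that each of the 3 experiments gave all 4 compartments, and the replicate number was read as that experiment. Deviations from the compartment means were compared as a check. Over the 18 pairs of arrays with the same number their correlation ranged from -0.063 to 0.105 with a mean of 0.021. The mean for arrays with different numbers was -0.010. It is no separate comparison, because deviations from a compartment mean sum to 0 and so largely set it. With its own number, rather than another, 10 of the 12 arrays correlated best, and the number expected without any pairing was not worked out.

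Gene lists of pathways and cell type markers, 30 lists with 746 genes, were fixed before the data were examined, as were the rule for named genes, the tests and the alternatives, except where stated. Of these genes, 638 matched a probe set. The members of all lists, those described as published included, were written from general knowledge of the field and not checked against a source here, so that what the published lists stand for rests on recall. The lists covered genes published for the left or right dorsal mesentery, the left-determining Nodal cascade, Wnt ligands and receptors, Wnt antagonists and targets, planar polarity and formins, BMP and TGF-beta signalling, hyaluronan and matrix proteoglycans, collagens and matrix glycoproteins, basement membrane, cadherins, retinoic acid, hedgehog, FGF and Notch, guidance cues, smooth muscle and actomyosin, cell cycle, immediate early and stress genes, glycolysis and hypoxia, and HOX genes. Marker lists covered coelomic epithelium, mesenchyme, endothelium, blood cells, endoderm, neural crest and enteric neurons, germ cells, gonad with adrenal and nephros, neural tube with notochord and muscle, and liver. A gene was represented by its tested probe set of highest mean signal, which gave 9735 genes. Lists with at least 5 measured genes were tested with camera at its preset correlation of 0.01 and with a correlation estimated from the data. They were also tested with fry, which asks only whether a list moves on balance in one direction. All were adjusted over the 30 lists of a contrast. For some lists that lost a call in the second setting the estimated correlation was below 0.01, such as basement membrane (-0.024) and germ cells (-0.011). A higher correlation between genes cannot have ended those calls. In the second setting camera also refers its statistic to the 6 residual degrees of freedom, rather than to the number of genes. That alone raises p, so a call lost there need not reflect correlation between genes. The list for the left side went in the mesenchyme from camera adjusted p = 4.7e-14 to 0.0052 at an estimated correlation of -0.053.

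Named genes were, per contrast, the 10 with the largest change in each direction (5 for the interaction) among those past the threshold with 1 symbol not beginning with LOC and the same sign in all 3 experiments. To these were added all members of both published lists and up to 4 members per list with the smallest p. Log2 changes are given ± the standard error of the model, and signals as mean ± SD over n = 3 arrays. Folds were computed from the log2 changes.

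The code was tested on simulated data, with 200 of 23063 probe sets changed. Changes of 2-fold and 4-fold were recovered in 37% and 93% of cases for the mesenchymal left-right contrast, where false calls made up 3.70% of calls. The recoveries were 42% and 91% for the epithelial left-right contrast (6.34% false), 73% and 100% for the layers (4.42% false), and 23% and 68% for the interaction (4.21% false). In a simulation of 9735 genes, camera called the 1 list that had been shifted by 0.5 log2, and no other, in each of the 4 contrasts. All simulated values were drawn independently for each gene and array, in 1 run per contrast. They held no correlation between genes, no effect of the experiment and the same spread on all arrays. The simulations thus test the code and do not give the rate of false calls, of lists above all, on the real arrays.

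Alternatives were no block, the experiment as a random block, quantile normalization, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, no intensity trend, array weights, a 2-fold minimum, only the arrays compared, and leaving out each experiment or each array in turn. An alternative without both arrays that lay farthest from the rest, right mesenchyme 3 and right epithelium 3, was added after the data were seen. Coordinates were not used here, and no sample was left out.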

Results

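Left and right epithelium and left and right mesenchyme of the dorsal mesentery were each represented by 3 arrays, 1 from each of 3 biological experiments. Pairwise correlations of the 12 arrays over all probe sets lay between 0.926 and 0.966. The median SD between the arrays of a compartment was 0.273 log2 in left epithelium, 0.250 in left mesenchyme, 0.264 in right mesenchyme and 0.288 in right epithelium. Right epithelium 3 and right mesenchyme 3 lay farthest from the rest, with residual SDs of 0.468 and 0.441 log2 against 0.364 to 0.411 on the other arrays. RNA integrity was gauged from the 3 prime minus 5 prime signal of control probe sets. For GAPDH it was 0.17 log2 higher on the 6 left than on the 6 right arrays (exact two-sided permutation p = 0.043, adjusted p = 0.17 over 4 such tests), and for actin 0.09 log2 higher (exact permutation p = 0.51).

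The left and right mesenchyme were compared to find genes that differ between the sides of a tissue whose asymmetric change tilts the gut tube at about this stage. CDH6 and CDH20, which encode type II cadherins, rose on the left by 2.64 ± 0.20 log2 (6.23-fold, adjusted p = 5.1e-07) and 2.86 ± 0.33 log2 (7.27-fold, adjusted p = 7.5e-05). FAS, the gene of a death receptor, rose from 35.6 ± 10.1 on the right to 434 ± 52.5 on the left. ENPEP, which encodes an aminopeptidase that cleaves angiotensin II, was 18.0-fold lower on the left (-4.17 ± 0.28 log2, adjusted p = 2.2e-07), with a signal of 36.7 ± 10.3 against 927 ± 126. PTPRO, the gene of a receptor tyrosine phosphatase, fell from 2880 ± 334 on the right to 421 ± 104 on the left.

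In this comparison 460 probe sets passed, 215 higher and 245 lower on the left, and 263 of them, 139 higher and 124 lower, changed at least 2-fold. They belonged to 292 named genes, and 91 had no single symbol. All 460 had the same sign in the 3 experiments. Further large rises were those of FAM19A1 (3.26 ± 0.41), SST1 (2.63 ± 0.35), the water channel gene AQP1 (2.52 ± 0.30), ASIC2 (2.36 ± 0.28), HES5 (2.33 ± 0.41) and GJA5 (2.18 ± 0.49), an arterial connexin. The list of endothelial markers, to which GJA5 does not belong here, was higher on the same side (median 0.84, 5 of 22 passing). SST1 was far dimmer in the mesenchyme, at 360 ± 242 on the left and 38.1 ± 11.7 on the right. It was at 2967 ± 949 in left and 393 ± 51.4 in right epithelium. Epithelium cut along with the mesenchyme was not excluded as the source of its mesenchymal rise. Further large falls were those of SEMA3E (-2.52 ± 0.30), a secreted guidance factor, IGSF11 (-2.44 ± 0.41), WISP1 (-2.05 ± 0.40), HNMT (-2.02 ± 0.35), CLBA1 (-1.97 ± 0.25), ADAMTSL3 (-1.96 ± 0.35), PCLO (-1.93 ± 0.38) and PERPB (-1.89 ± 0.21). FAM19A1 was above the floor on 1 of 3 right mesenchymal arrays, HES5 on 2 of 3, and ENPEP and HNMT on 2 of 3 left ones. Without an intensity trend 205 probe sets passed, 106 higher and 99 lower, and with array weights 763. Leaving out both right mesenchyme 3 and right epithelium 3 gave 288 (152 higher and 136 lower), leaving out an experiment 148 to 225, and leaving out any single mesenchymal array 239 to 279. The balance of rises and falls thus depended on these settings. GJA5, PCLO, WISP1, HES5 and ADAMTSL3 lost their call without a single array in at least 1 case, with adjusted p = 0.21 for GJA5 without right mesenchyme 2.

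Of 7 measured genes listed from general knowledge as published for the left dorsal mesentery, with no source checked here, 6 rose on the left and 1 did not pass. Adjusted over the list alone, all 7 rose. ISL1, which encodes a LIM homeodomain factor, rose by 2.30 ± 0.26 log2, from 202 ± 33.6 to 1062 ± 171. CXCL12, the gene of a chemokine, rose by 1.57 ± 0.13 log2 to 9028 ± 441, and GPC3, a glypican gene, by 1.62 ± 0.18. The formin gene DAAM2 rose by 0.98 ± 0.24 (adjusted p = 0.047, but 0.20 without the experiment as a block), and the Wnt receptor genes FZD4 and FZD8 by 0.78 ± 0.17 and 0.74 ± 0.16. Another probe set of FZD8 had the opposite sign. CDH2, the N-cadherin gene, differed by 0.57 ± 0.17 (adjusted p = 0.12). Of 6 genes listed in that way for the right side, 3 fell on the left, also adjusted over the list alone: TBX18, a T-box factor gene, by -1.57 ± 0.21 log2, TNFAIP6, whose product modifies hyaluronan, by -1.88 ± 0.36, and SFRP1, a Wnt antagonist, by -0.68 ± 0.16. SFRP2 (-0.28), BMP4 (-0.84) and HAS2 (0.08) did not pass. Both lists were called by camera (adjusted p = 4.7e-14 and 3.4e-05, and adjusted p = 0.0052 and 0.024 with an estimated correlation). Their members may have been chosen on these very samples, so neither the direction nor the counts are independent evidence. DAAM2, FZD4, FZD8, TNFAIP6 and SFRP1 were lost when single arrays were left out, with adjusted p up to 0.24 for DAAM2 without left mesenchyme 1 and 0.19 for SFRP1 without right mesenchyme 3.

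Markers of endothelium were higher in the left mesenchyme. Over the 22 measured genes the median change was 0.84 log2, 5 rose, 0 fell and 17 did not pass (11 higher and 1 lower adjusted over the list alone). The call held with an estimated correlation (camera adjusted p = 7.3e-06, estimated 0.016). VE-cadherin (CDH5) rose by 2.09 ± 0.25 log2, from 805 ± 29.3 to 3491 ± 251, SOX7 by 1.96 ± 0.28, VWF by 1.77 ± 0.34 and CLDN5 by 1.74 ± 0.30, and LMO2, named after its value was seen, by 1.24 ± 0.28. VWF was lost without 3 of the single arrays, with an adjusted p of up to 0.067 (without right mesenchyme 2). Blood cell markers had a median of -0.16 with 0 of 10 passing (adjusted p = 0.41). Of the lists for other cells that a section could hold, camera called that of germ cells (adjusted p = 0.00077) and not 5 others, with adjusted p = 0.60 for endoderm (1 of 9 fell, GATA4), 0.98 for neural crest (NEFM rose and TH fell among 9, calls that ended without single arrays with adjusted p up to 0.15 for NEFM), 0.81 for neural tube, notochord and muscle (0 of 5), 0.41 for liver (0 of 8) and 0.069 for gonad, adrenal and nephros (2 of 6 fell, LHX9 and GATA4), although fry called the last (adjusted p = 0.025).

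Genes of the cell cycle were higher on the left, with 4 of 31 rising, 1 falling and a median of 0.37 log2 (17 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.1e-09, adjusted p = 0.016 with an estimated correlation). The proliferation marker MKI67 rose by 0.73 ± 0.12, E2F1 by 0.92 ± 0.15, TYMS by 0.67 ± 0.16 and BUB1B by 0.37 ± 0.09, while the single member that fell, named after its value was seen, was the cyclin gene CCND2 (-0.61). Germ cell markers were higher too (median 0.48; 2 of 12 rose, 2 adjusted over the list alone; adjusted p = 0.00077, and 0.038 estimated). Their risen members were DAZL (0.52 ± 0.11) and CXCR4 (1.47 ± 0.27), the receptor of CXCL12, which is not specific to germ cells. Single arrays ended the calls of TYMS, BUB1B, DAZL and CXCR4, with adjusted p up to 0.25 for BUB1B without right mesenchyme 2.

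The list of collagens and matrix glycoproteins was lower on the left. Its median was -0.26, with 1 of 29 rising (COL14A1, 1.62 ± 0.34) and 2 falling (COL3A1, -0.69 ± 0.12, and POSTN, -0.68 ± 0.14). Adjusted over the list alone 7 fell and 1 rose, and the call held with an estimated correlation (adjusted p = 0.00035, and 0.024 estimated). For basement membrane the median was -0.25, LAMA5 rose (0.91 ± 0.18) and ITGA6 fell (-0.97 ± 0.09) among 22, 1 rose and 2 fell over the list alone, and the call (adjusted p = 0.028) gave adjusted p = 0.097 with an estimated correlation. For smooth muscle and actomyosin the median was -0.28, VIM fell (-0.36 ± 0.07) among 13, 5 fell over the list alone, and the call (adjusted p = 0.00035) gave adjusted p = 0.058 with an estimated correlation. POSTN had an adjusted p of 0.055 without the block. COL14A1, COL3A1, POSTN, LAMA5 and VIM were lost without single arrays, with adjusted p up to 0.12 for LAMA5 without left mesenchyme 3.

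Several single genes of lists that camera did not call also passed in the mesenchyme. In retinoic acid signalling (13 genes, adjusted p = 0.23) RDH10, whose product makes retinal, rose by 1.28 ± 0.12 and CYP26A1, whose product degrades retinoic acid, by 1.46 ± 0.17, while ALDH1A2, whose product makes retinoic acid, fell by 0.75. In the list of hyaluronan and proteoglycans (18 genes, adjusted p = 0.41, median 0.14 but mean -0.03) versican (VCAN) rose by 1.76 ± 0.15, SPOCK1 by 1.00 and LUM by 0.90, and TNFAIP6 fell. LUM had an adjusted p of 0.059 without the block and 0.21 without left mesenchyme 3. Of 35 guidance genes 5 rose, among them CXCL12, CXCR4 and NRP2 (1.43), and 3 fell, among them SEMA3E and SEMA5A (-1.39; list adjusted p = 0.54). Of 24 FGF and Notch genes HES5 and HEY1 rose and FGF10 and FGFR2 fell (0.48), and of 29 BMP and TGF-beta genes TGFB2, LTBP1 and CHRDL1 rose and SMAD6 fell (0.74), with CHRDL1 at adjusted p = 0.053 without the block. Leaving out a single array ended the calls of HES5, HEY1, FGF10, FGFR2, TGFB2, CHRDL1 and CXCR4 in at least 1 case, with adjusted p up to 0.26 for CHRDL1 without left mesenchyme 3.

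The remaining lists were likewise not called by camera in the mesenchyme, where fry called 10 lists against the 8 of camera, among them cadherins (adjusted p = 0.0079). By camera the adjusted p was 0.62 for the Nodal cascade (0 of 9 passing), 0.37 for Wnt ligands and receptors (3 of 25 rising), 0.61 for Wnt antagonists (2 of 16 falling), 0.76 for planar polarity (DAAM2 rose and PRICKLE1 fell among 18, the latter with adjusted p = 0.077 without right mesenchyme 2) and 0.74 for cadherins (3 of 28 rising, 1 falling). It was 0.79 for hedgehog genes (0 of 8), 0.41 for immediate early and stress genes (0 of 14), 0.48 for glycolysis (0 of 20), 0.81 for HOX genes (0 of 21), 0.19 for coelomic epithelium (1 of 22 rising, 3 falling) and 0.37 for mesenchyme markers (2 of 23 rising, 4 falling).

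The left and right epithelium were compared to ask the same question of the covering layer. CDH6 rose on the left by 3.44 ± 0.20 log2 (10.8-fold, adjusted p = 2.5e-08), from 127 ± 21.0 to 1523 ± 127, FAS by 3.53 ± 0.32 and versican (VCAN) by 2.24 ± 0.15, from 1085 ± 262 to 5097 ± 295. ENPEP was 16.1-fold lower on the left (-4.01 ± 0.28 log2, adjusted p = 1.8e-07), at 119 ± 39.8 against 2112 ± 267, and PTPRO fell by 2.27. The hormone gene SST1, for somatostatin, rose from 393 ± 51.4 to 2967 ± 949, by 2.81 ± 0.35 log2.

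In the epithelium 569 probe sets passed, 231 higher and 338 lower on the left, belonging to 344 named genes, with 332 changed at least 2-fold and 123 without a single symbol. Of the 569, 567 had the same sign in all 3 experiments. Other large rises were those of VIPR2 (2.59 ± 0.36), a receptor of vasoactive intestinal peptide, MGP (2.39 ± 0.31), CDH20 (2.37 ± 0.33), ABCC9 (2.24 ± 0.26), SLC9A9 (2.18 ± 0.27) and NTRK3 (2.14 ± 0.47). Other large falls were those of CRHBP (-3.02 ± 0.38), IGSF11 (-2.79 ± 0.41), SMYD1 (-2.78 ± 0.30), FAM198B (-2.44 ± 0.51), SCGN (-2.42 ± 0.33), TH (-2.40 ± 0.37), FABP1 (-2.37 ± 0.41) and LRAT (-2.27 ± 0.31), the gene of a retinol esterifying enzyme. FAS was above the floor on 1 of 3 right epithelial arrays, MGP and NTRK3 on 2 of 3, CRHBP, FAM198B and TH on 1 of 3 left ones, and IGSF11 and FABP1 on 2 of 3. NTRK3 had an adjusted p of 0.064 without the block, and 0.15 without left epithelium 3. FAM198B had 0.10 without the same array. With only the 6 epithelial arrays in the fit 289 probe sets passed, without an intensity trend 268, without experiment 1 or 2 259 and 199, and without left epithelium 2, left epithelium 3, right epithelium 2 or right epithelium 3 the count was 323, 323, 338 and 366.

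Of the 7 genes listed for the left side, 4 rose in the epithelium, 4 also adjusted over the list alone: ISL1 (2.13 ± 0.26), CXCL12 (2.08 ± 0.13, from 1572 ± 372 to 6566 ± 344), GPC3 (1.92 ± 0.18) and DAAM2 (1.03 ± 0.24, adjusted p = 0.030, and 0.15 without the block). FZD4 (0.40), FZD8 (-0.18) and CDH2 (-0.00) did not pass. Of the 6 genes listed for the right side, 3 fell, 3 also adjusted over the list alone: TBX18 (-2.04 ± 0.21, at 609 ± 240 against 2447 ± 426), SFRP2 (-0.93 ± 0.18) and TNFAIP6 (-1.41 ± 0.36, adjusted p = 0.049). The caution given for these lists applies again. Both were called (adjusted p = 4.7e-07 and 4.3e-05, and adjusted p = 0.034 and 0.035 with an estimated correlation). DAAM2, SFRP2 and TNFAIP6 were lost without single arrays, with adjusted p up to 0.26 for TNFAIP6 without left epithelium 3.

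Hyaluronan and proteoglycan genes were higher in the left epithelium, with 4 of 18 rising, 1 falling and a median of 0.34 (5 and 1 adjusted over the list alone; adjusted p = 0.00092, and 0.045 estimated). Versican (VCAN) rose as above, lumican (LUM) by 1.88 ± 0.20, SPOCK1 by 1.72 ± 0.17 and decorin (DCN) by 0.51 ± 0.13, DCN with an adjusted p of 0.13 without the block and 0.22 without left epithelium 2, and TNFAIP6 fell. Cell cycle genes were higher on the left, with 4 of 31 rising (TTK 0.85, TYMS 0.62, CENPF 0.47, BUB1B 0.36), 0 falling and a median of 0.33 (11 higher and 1 lower adjusted over the list alone; adjusted p = 4.7e-07, and 0.035 estimated). Each of these 4 was lost without at least 1 array, with adjusted p up to 0.24 for TYMS without left epithelium 3, and CENPF had 0.051 without the block. Collagens and matrix glycoproteins were lower, with 4 of 29 falling (POSTN -0.80, SPARC -0.68, COL1A1 -0.56, COL5A1 -0.39), 0 rising and a median of -0.27 (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.0020, and 0.045 estimated). The calls of COL1A1 and COL5A1 ended without single arrays, with adjusted p = 0.084 and 0.13 without left epithelium 3.

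Lists of other cell types moved in the epithelium, but none of these calls held with an estimated correlation. That correlation was above the preset 0.01 for blood cells (0.15), mesenchyme markers (0.026) and smooth muscle (0.040). It was below 0.01 for coelomic epithelium (0.0098), germ cells (-0.011) and basement membrane (-0.024), whose calls a higher correlation cannot have ended. Blood cell markers were lower on the left, with 5 of 10 falling (5 adjusted over the list alone) and a median of -0.79 (adjusted p = 1.8e-06, and adjusted p = 0.051 with an estimated correlation). The 5 were globin genes, HBA1 (-1.43 ± 0.26), HBZ (-1.41 ± 0.24), HBBR (-1.16 ± 0.22), HBE (-1.10 ± 0.19) and, named after its value was seen, HBAD (-1.14), and the signal of HBZ was 5653 ± 4551 against 12359 ± 644. HBZ had an adjusted p of 0.12 without experiment 2, and HBBR 0.064 without left epithelium 2. The fall lay mainly on left epithelium 2 and 3, where the median globin signal was 4914 and 4278. It was 12749 on left epithelium 1 and 13959 to 15286 in right epithelium. Mesenchyme markers had 3 of 23 rising, LUM among them, and 4 falling, TBX18 and VIM among them, 4 and 11 adjusted over the list alone, and a median of -0.35 (adjusted p = 0.0023, and adjusted p = 0.080 with an estimated correlation). Coelomic epithelium markers had 3 of 22 falling (TCF21 -1.47, ITGA6 -0.83, ALDH1A2 -0.69), 3 over the list alone, and a median of -0.06 (adjusted p = 0.038, and adjusted p = 0.13 with an estimated correlation). Germ cell markers had 1 of 12 rising (DAZL 0.48), 1 over the list alone, and a median of 0.41 (adjusted p = 0.0022, and adjusted p = 0.051 with an estimated correlation). Smooth muscle and actomyosin had 1 of 13 falling (VIM -0.46), 3 over the list alone, and a median of -0.19 (adjusted p = 0.00081, and adjusted p = 0.060 with an estimated correlation). Basement membrane had 2 of 22 rising (FREM2, LAMA5) and 2 falling (ITGA6, COL4A1), 2 and 6 over the list alone, and a median of -0.14 (adjusted p = 0.038, and adjusted p = 0.11 with an estimated correlation). Endothelial markers had a median of -0.17, with 1 of 22 passing (adjusted p = 0.85), FLT1 (-1.14), which had an adjusted p of 0.11 without right epithelium 2. Without left epithelium 3, TCF21, DAZL, FREM2, LAMA5, COL1A1 and COL4A1 were not called, with adjusted p up to 0.17 for COL4A1 and DAZL.

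The other 18 lists were not called by camera in the epithelium, with adjusted p from 0.12 (gonad, adrenal and nephros) to 0.97. Fry called 12 lists against the 11 of camera, and the one added was that of neural crest and enteric neurons (adjusted p = 0.0020, and 0.26 by camera). Single members of them passed all the same. CYP26A1 rose by 1.16 ± 0.17 log2 and LTBP1, whose product binds TGF-beta, by 1.04 ± 0.09. EDNRB, an endothelin receptor of neural crest, fell by 1.39, the cadherin gene CDH11 by 1.22 and RSPO3, which encodes an enhancer of Wnt signalling, by 1.01.

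The overlap between the layers was tested directly, on contrasts that share no array but share the estimate of spread of each probe set. Of the probe sets called in both layers 93 were higher on the left in both, where 2.15 would be shared by independent lists, and 139 were lower in both, where 3.59 would be shared. Only 1 had opposite signs, against 5.60. CXCL12, ISL1, CDH6, FAS and VCAN were among the genes higher on the left in both layers, and ENPEP, PTPRO, TBX18 and SEMA3E among those lower. In the epithelium SEMA3E had an adjusted p of 0.0078, and 0.053 without the block. Across the 23063 probe sets, which are not independent replicates, the left-right changes of the layers correlated with r = 0.370 (Spearman rho = 0.279), and 59.7% had the same sign. Over the probe sets called in the mesenchyme r was 0.839, with 435 of 460 of the same sign, and over those called in the epithelium 0.853, with 530 of 569.

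**Figure D1:**
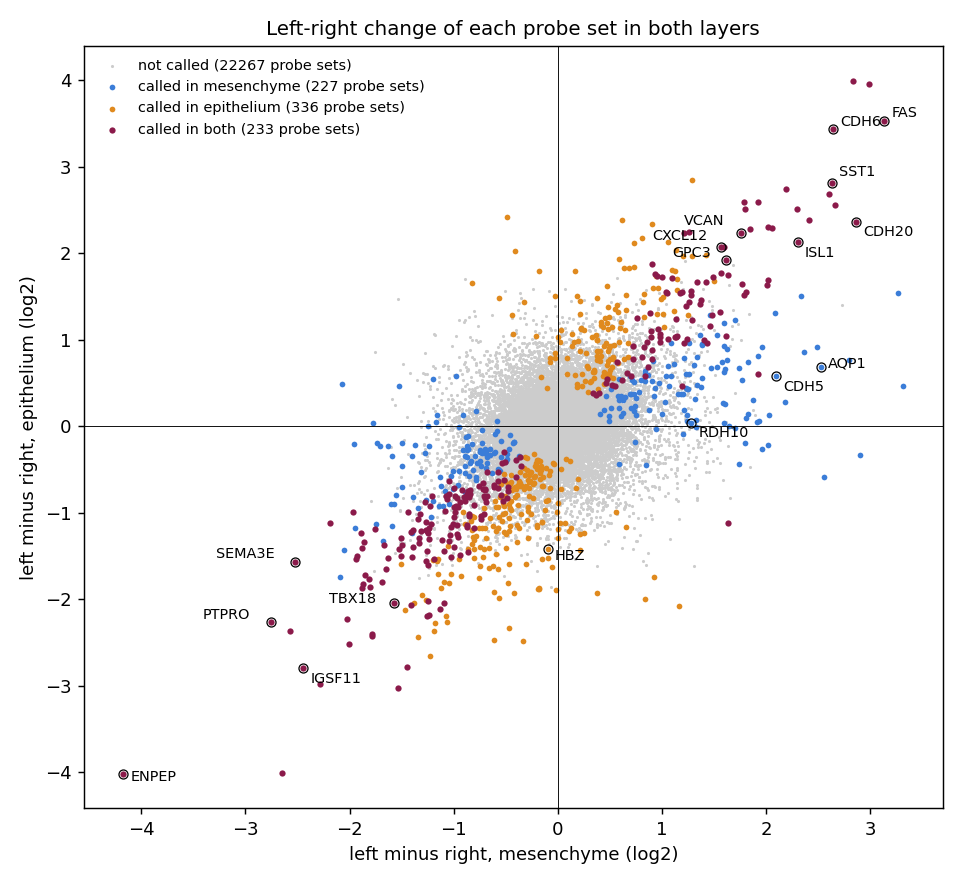
Left minus right change of each of the 23063 tested probe sets in the mesenchyme (x axis, log2) and in the epithelium (y axis, log2), coloured by the layer in which it passed adjusted p 0.05. Named genes are ringed, with CDH6, FAS and ENPEP far from 0 in both layers and CDH5 and RDH10 displaced along the mesenchymal axis.

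Whether the left-right change differed between the layers was tested with the interaction, which 6 probe sets passed (1346 at an unadjusted p under 0.05), 3 of them without a single symbol. RDH10 was the one gene named by the rule. Its signal was 8418 ± 841 in left epithelium, 7748 ± 605 in left mesenchyme and 8264 ± 1736 in right epithelium, but 3180 ± 189 in right mesenchyme, an interaction of -1.24 ± 0.17 log2 (adjusted p = 0.012). Its probe set can bind similar transcripts, and its 3 other probe sets had the same sign. The call was lost without experiment 2 (adjusted p = 0.38), without left mesenchyme 2 (0.062) and without left mesenchyme 3 (0.055). The other named probe sets, LOC419390 (-2.85 ± 0.39) and LOC101749175 (-3.23 ± 0.48), were brightest in left mesenchyme, at 3451 ± 406 and 658 ± 74.0. The matrix protease gene MMP28 came next (-2.66 ± 0.46) and did not pass (adjusted p = 0.055). FZD8 (-0.91) and FZD4 (-0.38) did not pass it. As lists, endothelial markers had a lower left-right change in the epithelium (median -0.91, adjusted p = 1.8e-07, and 0.021 estimated), with 0 of 22 members passing singly and 3 lower adjusted over the list alone. Their median signal was only 90.3 to 148 on the epithelial arrays, against 233 to 594 on the mesenchymal ones. The epithelium thus held little endothelial signal in which a change could show. The blood cell list (median -0.62, adjusted p = 0.00016) gave adjusted p = 0.24 with an estimated correlation, and hyaluronan and proteoglycans (median 0.43, adjusted p = 0.0021) gave adjusted p = 0.11. In the blood cell list 0 members passed singly and 5 adjusted over the list alone, and in that of hyaluronan and proteoglycans 0 by either count. The other 27 lists were not called by camera or fry, and fry did not call the blood cell list either (adjusted p = 0.28).

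Epithelium and mesenchyme were compared over both sides to show what separates the layers. Podocalyxin (PODXL), a surface sialomucin of epithelia, was higher in the epithelium, at 5452 ± 308 and 6597 ± 646 in left and right epithelium against 1958 ± 183 and 1787 ± 67.2 in left and right mesenchyme (1.67 ± 0.08 log2, 3.19-fold, adjusted p = 2.1e-09). FGF9, the gene of a secreted growth factor, was higher by 2.36 ± 0.27 log2 (5.15-fold, adjusted p = 3.6e-05), and SST1 by 3.03 ± 0.25. VE-cadherin (CDH5), a junction protein of endothelium, was lower in the epithelium by 6.16-fold (-2.62 ± 0.18 log2, adjusted p = 1.3e-07), and the lysozyme gene LYG2 had a change of -3.33 ± 0.29.

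Of 1105 probe sets that passed, 461 were higher and 644 lower in the epithelium, 399 of the 1105 changed at least 2-fold, and they belonged to 694 named genes, with 223 lacking a single symbol. The sign was the same in all 3 experiments for 1103. Other large differences were those of CYGB (2.14 ± 0.20), SFRP4 (1.95 ± 0.43), SPP2 (1.90 ± 0.22), EMP1 (1.85 ± 0.28), EEF1A2 (1.83 ± 0.29), SLC25A48 (1.72 ± 0.32) and the polarity gene PARD6B (1.52 ± 0.21). On the mesenchymal side they were those of GJA5 (-3.13 ± 0.35), LECT2 (adjusted p = 5.2e-07), the antimicrobial peptide genes AvBD7, AvBD1 and DEFB4A (-2.89, -2.83 and -2.82), FNDC1 (-2.68 ± 0.30), AQP1 (-2.59 ± 0.21) and CXorf36 (-2.45 ± 0.28). SLC25A48 was above the floor on 0 of 3 left and 2 of 3 right mesenchymal arrays, EMP1 on 1 of 3 of either side, FGF9 on 1 of 3 and EEF1A2 on 2 of 3 right ones, and SFRP4 on 1 of 3 left and 2 of 3 right ones. In the epithelium LYG2 and GJA5 were above it on 2 of 3 left and 1 of 3 right arrays, AvBD1 and FNDC1 on 2 of 3 of either side, and AvBD7 on 1 of 3 right ones. Without an intensity trend 672 probe sets passed, and without experiment 1, 2 or 3 the count was 512, 418 and 696.

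Marker lists of the captured layers separated as named. Of 22 coelomic epithelium markers 9 were higher in the epithelium, 1 lower and 12 did not pass (10 and 2 adjusted over the list alone; median 0.20, adjusted p = 2.4e-08, and 0.010 estimated). Among the 9 were the keratins KRT24 (1.19 ± 0.08) and KRT7 (0.79 ± 0.07), and the lower one was CLDN5, a claudin of endothelium. Of 23 mesenchyme markers 7 were lower and 0 higher (12 and 0 over the list alone; median -0.35, adjusted p = 1.4e-08, and 0.013 estimated), including the transcriptional repressors SNAI2 (-1.01 ± 0.10) and ZEB2 (-0.82 ± 0.11) and LUM (-1.67 ± 0.14). Of 22 endothelial markers 15 were lower and 0 higher in the epithelium (19 over the list alone; median -1.09, adjusted p = 1.2e-19, and 0.0014 estimated), among them SOX7 (-1.97 ± 0.20), FLI1 (-2.02 ± 0.24) and CLDN5 (-2.20 ± 0.21). Hyaluronan and proteoglycan genes were lower too, 7 of 18, with 1 higher (7 and 1 over the list alone; median -0.28, adjusted p = 3.8e-05, and 0.016 estimated), including LUM, the link protein gene HAPLN1 (-1.43 ± 0.12) and VCAN (-0.71 ± 0.11). Cell cycle genes were higher, 11 of 31 with 0 lower (22 over the list alone; median 0.29, adjusted p = 2.2e-11, and 0.010 estimated).

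A further 5 lists were called between the layers and not with an estimated correlation. Of 10 blood cell markers 3 were lower in the epithelium (4 over the list alone; median -0.24, adjusted p = 0.0010, and adjusted p = 0.14 with an estimated correlation), namely SPI1 (-2.20 ± 0.23) and CSF1R (-1.81 ± 0.20), both of macrophages, and ALAS1, an enzyme of heme synthesis. Of 13 smooth muscle and actomyosin genes 3 were lower, MYOCD (-1.40), CALD1 (-0.40) and ACTN1 (-0.32), with 8 lower and 1 higher over the list alone (median -0.23, adjusted p = 0.0010, and adjusted p = 0.090 with an estimated correlation). Of 24 FGF and Notch genes 2 were higher, FGF9 among them, and 6 lower, among them LFNG (-1.29) and HES5 (-1.80), with 2 and 7 over the list alone (median -0.12, adjusted p = 0.042, and adjusted p = 0.13 with an estimated correlation). Of 6 gonad, adrenal and nephric markers 3 were higher, LHX9 (1.04 ± 0.11), EMX2 (1.41 ± 0.22) and PAX2 (1.19 ± 0.28), with 3 higher and 1 lower over the list alone (median 0.53, adjusted p = 0.022, and adjusted p = 0.14 with an estimated correlation). Of 12 germ cell markers DAZL was higher (0.31), with 1 higher and 1 lower over the list alone (median 0.24, adjusted p = 0.029, and adjusted p = 0.13 with an estimated correlation). ALAS1 had an adjusted p of 0.093 without the block and was lost without 10 of the 12 single arrays, and ACTN1, DAZL and PAX2 were lost without 8, 7 and 5 of them, with adjusted p up to 0.10 for ACTN1 without right mesenchyme 3. The other 20 lists were not called by camera. Of these fry called 5, namely neural crest (adjusted p = 0.0021), cadherins (0.0054), guidance cues (0.0098), genes listed for the left side (0.024) and collagens (0.033).

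**Figure D2:**
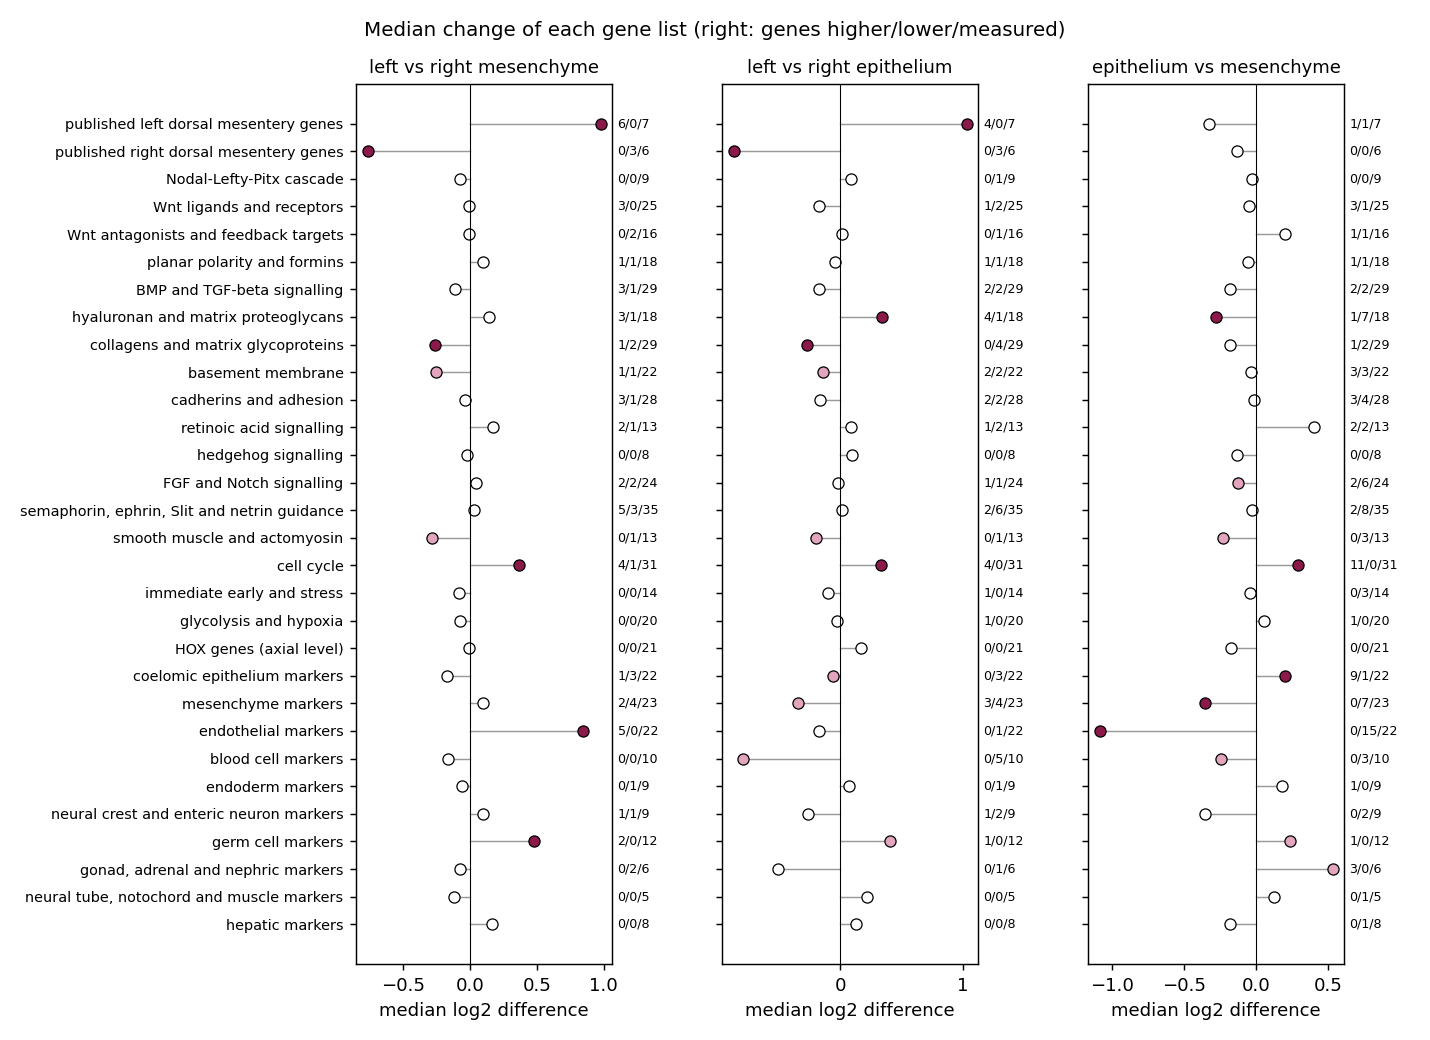
Median log2 change of each of the 30 gene lists (points, x axis) in the left-right contrast of the mesenchyme, that of the epithelium, and epithelium against mesenchyme, with the numbers of genes higher, lower and measured beside each point. Dark points were called with the preset and with the estimated correlation, pale points only with the preset one and open points with neither; endothelial markers have medians of 0.84, -0.17 and -1.09.

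**Figure D3:**
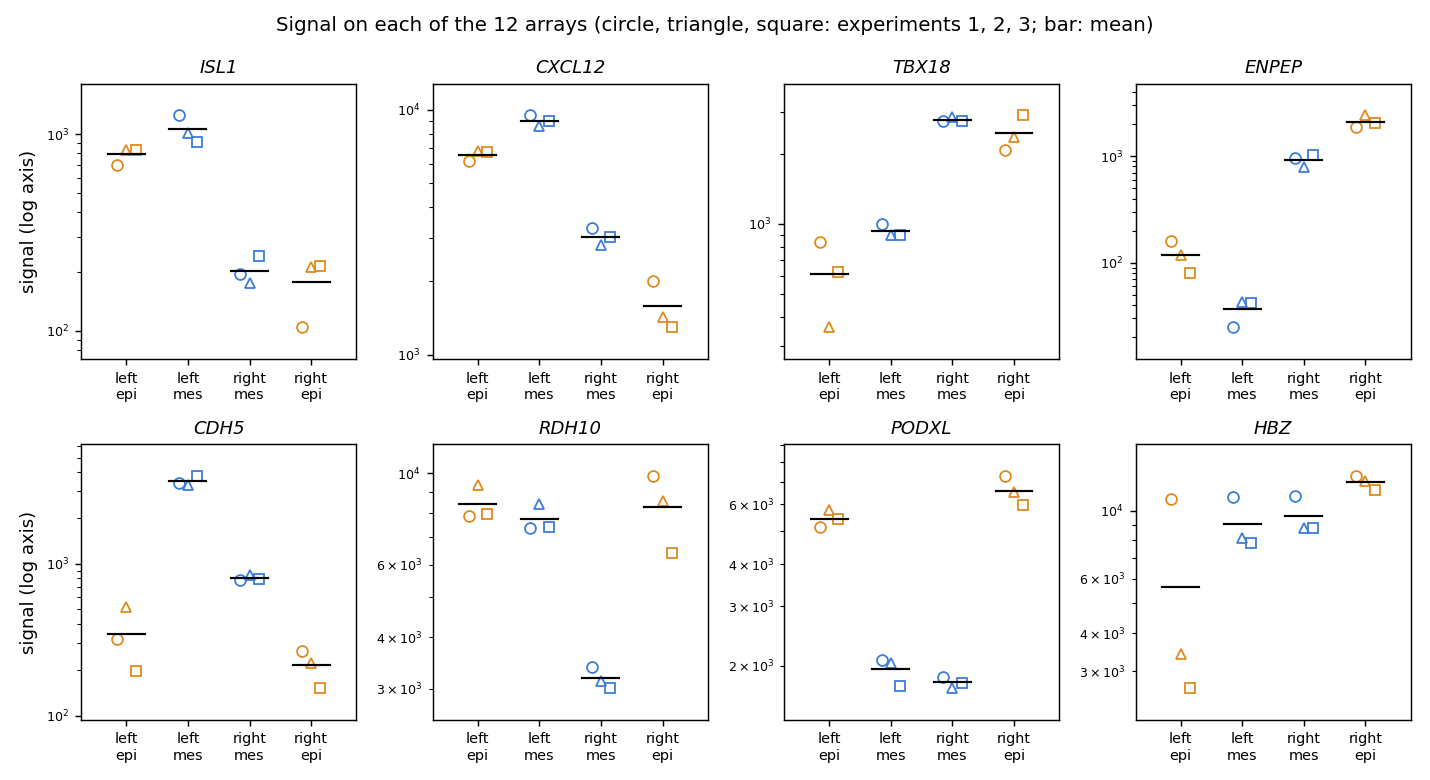
Signal on each of the 12 arrays (log axis) for ISL1, CXCL12, TBX18, ENPEP, CDH5, RDH10, PODXL and HBZ, with bars at the mean of a compartment and circles, triangles and squares for experiments 1, 2 and 3. ISL1, CXCL12, TBX18 and ENPEP separate the sides in both layers, and in HBZ left epithelium 1 lies apart from left epithelium 2 and 3, above both.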

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

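The tests of tissue carried over between the layers, of blood-filled vessels, of a lower share of the main cell type and of globin on single arrays were chosen after the results were seen, that of blood-filled vessels was read as open only once its value was known, and germ cell genes were added to that of a lower share after its first value was known.

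For 6 named results, 3 genes and 3 lists, the interaction passed the threshold. RDH10 had an interaction of -1.24 log2. The unnamed gene models LOC419390 and LOC101749175 had -2.85 and -3.23. The list medians of the interaction were -0.91 for endothelial markers (adjusted p = 0.021 with an estimated correlation), -0.62 for blood cell markers and 0.43 for hyaluronan and matrix proteoglycans. The last 2 lost their call with an estimated correlation (adjusted p = 0.24 and 0.11). For the endothelial markers, the low signal in the epithelium given in the report limits what the interaction can mean. Of 100 drawn splits of the arrays within each layer, 2 gave as many probe sets as the real split, itself included, against a real count of 6 and 10 for the highest other split. Such splits mix the sides within a layer, so that the left-right change common to both layers enters their spread, and they do not tell whether chance can be excluded for the interaction. Its count was 0 without an intensity trend and 0 without experiment 2 (limma, with 1346 at an unadjusted p under 0.05 when all arrays and the trend were used). The split that exchanges the sides in a single layer was not among those drawn.

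The left-right calls shared by both layers numbered 232. If mesenchyme cut along with the epithelium had brought them there, they would lie where endothelial RNA lies, at a median epithelium to mesenchyme ratio of 0.341 (upper quartile 0.497, 15 markers), but on their brighter side the shared calls had 1.00 (quartiles 0.808 and 1.25). For epithelium cut along with the mesenchyme the ratio was 0.996 (quartiles 0.802 and 1.24). That was above the 0.460 (upper quartile 0.676) of 9 coelomic epithelium markers. The 15 and 9 markers were those that had passed between the layers, a choice that by itself lowers their ratios. The shared calls in turn had to pass in both layers, a choice that by itself disfavours probe sets dim in either layer. Both ratios come from the same values, each being the reciprocal of the other, so they count as a single comparison. Chosen so, the shared calls were in the median about as bright in both layers, which does not decide on carry-over. Single members differed, such as SST1 with 360 ± 242 in left mesenchyme against 2967 ± 949 in left epithelium. With the GAPDH 3 prime to 5 prime difference as a covariate 97.7% of the change was left in the median (quartiles 91.6% and 104%). The median size was 1.19 log2 before and 1.14 after, which argues against RNA integrity as the whole cause. Of the 232 shared calls 117 were still called. The median SE grew from 0.182 to 0.204 and a residual degree of freedom was spent, but why calls were lost was not tested. A left-right identity held by both layers, which the design names, was not tested and stays open.

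Endothelial markers were higher in the left mesenchyme, with a median of 0.84 log2 over 22 genes. A lower share of the main cell type would raise the markers of all minor types alike, but 31 blood cell, neural crest and germ cell genes had a median of 0.21, and the difference of means of 0.67 had a two-sided permutation p of 0.0033 over genes, which are not independent (0.011 without the globin genes). The 19 blood cell and neural crest genes alone had a median of -0.15. The 12 germ cell genes alone had a median of 0.48, and the permutation test gave p = 0.29 for their difference from the endothelial genes. The values thus argue against a lower share as the whole cause and leave a part of it open. A larger captured area of blood-filled vessels would raise globin, and the 5 globin genes had a median of -0.15 (SD 0.171), but globin in the right epithelium was already 1.21 times that of the right mesenchyme, and such a baseline would hide a small share. That explanation therefore stays open. More endothelial cells on the left and more RNA per endothelial cell, both biological, were not tested.

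Globin genes were lower in the left epithelium. The median over the 5 genes, left minus right epithelium, was -0.25 log2 in experiment 1, -1.64 in experiment 2 and -1.89 in experiment 3. Their median signal was 12749 on left epithelium 1, but 4914 and 4278 on left epithelium 2 and 3, against 13959 to 15286 in right epithelium and 9442 to 12060 in mesenchyme. Whether this was red blood cell RNA differing between single arrays or a side difference seen in 2 of 3 experiments was not decided, because no test of it was independent of these values.

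For the left-right counts the splits are too few for a share under 0.05. The 10 splits of the 6 mesenchymal arrays gave 460 calls for the real one and at most 1 for another, with 1 split as large, the real one. The 10 splits of the 6 epithelial arrays gave 569 and at most 0, again with 1 as large. In each layer 4 of the 10 part all 3 pairs of an experiment as the real split does, and the others of these gave 0. For epithelium against mesenchyme, 1 of 100 drawn splits, the real one with 1105, was as large. The highest other gave 59. Chance is thus unlikely as the source of that count, though 100 draws cannot give a share below 1 of 100.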

How the results depend on the processing

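The alternative without both arrays farthest from the rest was chosen after the data were seen, and all others before. No called list or named gene turned its direction under the alternatives run on it. Of the counts, the excess of lower over higher calls in the mesenchyme (245 against 215) turned with a 2-fold minimum (124 lower and 139 higher), without an intensity trend (99 and 106), without both far arrays (136 and 152) and without right mesenchyme 3 (119 and 126), and was gone without experiment 2 (74 and 74). Of 225 called results of named genes, 221 stayed past the threshold under quantile normalization, 222 with a pseudocount of 1, 207 without a filter, 219 with array weights, and 178 of 223 without both far arrays. Only 133 did so without an intensity trend, and 132 to 154 without an experiment. The cause was not tested, except that leaving out arrays removes residual degrees of freedom.

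With no replicate block 447 probe sets passed in the mesenchyme, 529 in the epithelium, 1073 between the layers and 10 in the interaction, of which 422, 504, 1012 and 5 were calls with the block. The interaction also had 10 with the experiment as a random block (correlation -0.0061). Of the 225 called results, 16 were lost without the block. Besides those given with their values in the report these were JUN, ALDH1A3 and NEFM in the epithelium and JUN, WNT5A and KLF2 between the layers. A further 7 were called only without it, COL1A1 and COL4A1 in the mesenchyme, FGF9 in the epithelium, COL9A1 between the layers and PCDH9, MMP28 and SOX7 in the interaction.

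The left-right count of 460 in the mesenchyme became 205 without an intensity trend, 763 with array weights, 263 with a 2-fold minimum, 288 without both far arrays and 148 to 279 with an experiment or a mesenchymal array left out. The 569 in the epithelium became 268 without a trend, 332 with the 2-fold minimum, 289 with only the arrays compared and 199 to 437 with an experiment or an epithelial array left out. Arrays of the other layer enter these contrasts only through the experiment block and the shared spread, and without 1 of them the counts were 445 to 541 in the mesenchyme and 469 to 569 in the epithelium. The 1105 between the layers became 672 without a trend, 399 with the 2-fold minimum and 418 to 1148 with an experiment or array left out. The 6 of the interaction became 10 with quantile normalization, 10 with a pseudocount of 64, 10 with a filter at the 60th percentile, 3 without a filter, 14 with array weights, 0 without a trend and 0 to 15 with an experiment or array left out. With limma, 1346 passed at an unadjusted p under 0.05 in the main setting.

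With an estimated correlation the called lists went from 8 to 6 in the mesenchyme, from 11 to 5 in the epithelium, from 10 to 5 between the layers and from 3 to 1 in the interaction. With fry they were 10, 12, 15 and 2. Without an experiment they were 7 to 8, 7 to 10, 8 to 9 and 2 to 3, and 6 in the interaction with a filter at the 60th percentile. The correlation of the left-right changes, 0.370, was 0.339 with a pseudocount of 1, 0.412 with 64, 0.242 without a filter, 0.485 with the 60th percentile and 0.276 to 0.373 with an experiment or array left out, so dim probe sets near the floor lower it. List tests were not run with the random block or with single arrays left out. The estimated correlation also lowers the degrees of freedom of camera, so list calls lost with it need not reflect correlation between genes.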

Other observations

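The sets described here, probe sets that differed from each of the other 3 compartments past the threshold in a common direction, were chosen after the data were seen, and the test of other assignments was chosen before its result was seen. There were 253, of which 27 stood apart in 2 compartments. Left mesenchyme had 26 genes higher than in every other compartment. AQP1, at 1846 ± 168 against 314 ± 86.7 in right mesenchyme (SD, n = 3), differed from the nearest compartment by 2.52 log2. The Notch target HES5 did so by 2.21, the arterial connexin GJA5 by 2.18 and CDH5 by 2.09. EPAS1, a hypoxia-inducible factor abundant in endothelium, differed by 2.03, CD248 by 2.02, SOX7 by 1.96 and CD34 by 1.87. Its 20 lower genes included SPP2 (by 1.74) and ENPEP (1.33). Left epithelium had 15 genes higher than elsewhere, among them SST1 (2.81), the relaxin gene RLN3 (1.59), the cell cycle factor E2F8 (1.51) and LTBP1 (0.97), a binding protein of TGF-beta. Its 37 lower genes included MYL4 (2.04), MEF2C (1.87), FLT1 (1.69) and MMP28 (1.65). Where a gene had several such probe sets, that with the largest difference from its nearest compartment was taken. It need not be the representative probe set of the comparisons above, and for FLT1 it was another.

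Right mesenchyme had 18 genes higher than in the other compartments, among them the complement gene C7 (1.27), the serotonin receptor gene HTR2B (1.22) and MYL4 (1.10). Among its 20 lower genes were SST1 (2.63), RDH10 (1.33) and the guidance receptor genes NRP2 (1.32) and ROBO2 (1.21). For SST1, epithelium cut along with the mesenchyme was not excluded as a source of the mesenchymal values. The value of RDH10 is of another probe set than that of the left-right and interaction results. Right epithelium had 19 higher genes, among them the cation channel gene TRPC4 (1.43), NDNF (1.19), ENPEP (1.18) and RSPO3 (0.92). Its 23 lower genes included MGP (2.39), SLC9A9 (2.04), LUM (1.88) and PIEZO2 (1.83), a mechanically gated channel gene. ENPEP was thus lowest in left mesenchyme and highest in right epithelium. Some differences are approximate because the dim side lay near background. PIEZO2 and MGP were above the floor on 2 of 3 right epithelial arrays and ENPEP on 2 of 3 left mesenchymal ones. RLN3 was above it on 1 of 3 left mesenchymal, 2 of 3 right mesenchymal and 2 of 3 right epithelial arrays. HES5 was above it on 2 of 3 right mesenchymal and 0 of 3 right epithelial arrays. GJA5 and CD248 were above it on 2 of 3 left and 1 of 3 right epithelial ones. Of 100 drawn assignments of the 4 compartments within the experiments, 1, the real one, set 253 or more probe sets apart. The highest other gave 26. Other assignments mix the compartments, so that the differences between sides and layers enter their spread. They therefore do not tell whether chance can be excluded for probe sets set apart in a single compartment.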
